A study of Mus musculus with 12 samples.

How the data were processed

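RNA-seq was analysed for 12 libraries of mouse androgenetic haploid embryonic stem cells (ESCs), which carry a single chromosome set of paternal origin. Both parental lines, OdG and EG1, have a C57BL/6 background. The OdG table held 2 wild-type (WT) libraries and 2 libraries from each of 2 Etl4 knockout (KO) lines, here called line 1 and line 2. The EG1 table held 3 WT libraries and 3 libraries of 1 Etl4 KO line. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

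Per the labels' protocols, RNA was extracted with Trizol, 1 µg was used per library, and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA, HISAT2 2.1.0, featureCounts 1.6.4, DESeq2 and the mm10 build. The gene annotation, the filters and the strand setting used for counting are not given in the sources used here. The authors deposited whole-number counts per gene symbol, not normalized, in 2 tables of 24421 symbols each, over the same symbols in the same order. Each column was matched to a sample by its name and by the table that the sample's description names, and 0 columns were left unmatched. Total counts ran from 16110028 to 18774032 in the OdG table and from 17421260 to 19706599 in the EG1 table, so that 1 CPM (counts scaled to a common library total) stood for 16.1 to 19.7 counts. Replicates of every group differed by more than sampling noise (chi-square per degree of freedom 1.84 to 3.86), and each was counted as its own sample.

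The following choices were made before the data were examined: the groups, tests, gene lists, rule for named genes and alternatives, except where stated. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with 1 mean per group was fitted to each table. This left 14413 genes in the OdG table and 14016 in the EG1 table, with a biological coefficient of variation of 3.34% and 3.53%. OdG KO was the mean of the 2 KO lines on the log scale, so that each line weighed the same. The difference between parental lines was tested as an interaction in 1 fit over all 12 libraries and 14977 genes. All tests were two-sided. Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05, and every adjusted p given for a gene comes from edgeR's quasi-likelihood test. Values are CPM scaled within each table, as mean ± SD over 2 libraries per OdG group and 3 per EG1 group, and log2 fold changes with ± standard error (SE).

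Gene lists were tested with camera in limma 3.58.1 on voom values, which asks whether a list moved relative to the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. With an estimated correlation, camera also takes its degrees of freedom from the libraries and not from the genes. Those are few here, so a call lost in that setting need not come from correlation between genes. They also differ between fits, so calls held or lost do not rank OdG, EG1 and the interaction. Of 26 lists fixed in advance, 25 had at least 5 tested members. The list of mitochondrially encoded genes was not tested because the tables hold 0 such genes, and an analysis without those genes was not run for the same reason. The lists tested were core, naive, and formative and primed pluripotency, primitive endoderm, primitive streak and mesoderm, neural ectoderm, trophoblast, 2-cell-like, germline genes silenced by DNA methylation, glycolysis, nuclear oxidative phosphorylation, tricarboxylic acid cycle, p53 targets, G1/S and DNA replication, mitosis and cytokinesis, integrated stress response, hypoxia response, cholesterol synthesis, maternally and paternally expressed imprinted genes, fibroblast (feeder) markers, immediate early genes, epithelial adhesion, Wnt targets and MEK/ERK targets. List tests for line 2 versus line 1 and for the difference between parental lines were added after seeing the data. Chromosomes 1 to 19 and X were tested in the same way, with 23157 of the 24421 symbols placed by RefSeq coordinates of the mm10 assembly.

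Named genes followed a fixed rule. It took Etl4, then the 8 largest rises and 8 largest falls of OdG KO and of EG1 KO among called genes with at least 5 CPM in the higher group and every KO library on the same side of every WT library. It added the 6 largest shared changes per direction (by the smaller of the 2 changes), the 4 largest per direction for line 2 versus line 1 and for the interaction, and up to 4 members of each called list by adjusted p. Predicted genes with clone-style symbols were passed over. Genes named outside the rule are said to be so. A gene that the rule took is not reported here. Members of near-identical families (Zscan4, Usp17l, Tcstv, Rhox, Pramel) share reads, so their single values are uncertain, as are those of overlapping or antisense pairs such as Igf2 and Igf2os where counting may not have used strand.

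Calls shared by line 1 and line 2 were set beside 20 simulations of unchanged groups. All OdG libraries, WT included, were drawn around the mean of the 2 WT libraries, with the spread between libraries alone. Ratios of genes with few counts carry exact 95% Clopper-Pearson intervals, which cover counting error only. The pipeline was tested on simulated counts with 200 changed genes. For OdG KO versus WT, run on 14183 genes, 75.8% of 1.5-fold, 90.8% of 2-fold and 100% of 4-fold changes were recovered, with 7.9% false calls. For EG1, run on 13887 genes, these shares were 84.6%, 93.9% and 100%, with 2.7% false calls. For the interaction, run on 14611 genes, they were 56.9%, 77.3% and 90.9%, with 8.1% false calls. In each of the 3 simulations 0 of 20 unchanged lists were called. Genes were drawn independently there, so this does not test false calls of lists whose genes move together.

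The alternatives were DESeq2 1.42.0 (its size factors within edgeR, and its Wald test), no filter on low counts, a log2 fold change of at least 1, the 4 OdG KO libraries as a single group, fits of only the groups compared, both OdG KO lines required past the threshold, the replicate number as a block, an estimated inter-gene correlation, and each replicate left out in turn. A fit without Guf1, Gnpda2 and Tfap2c and fits of each OdG KO line against a single WT library were added after seeing the data. Trends with GC content, transcript length and expression were fitted with mgcv 1.9.3 using GENCODE transcripts of the same assembly.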

Results

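The study profiled mRNA in Etl4 KO and WT androgenetic haploid ESCs, and its title concerns a genetic screen in which Etl4 deficiency stabilised haploidy. Haploid ESCs tend to become diploid in culture, and Etl4 (also called Skt) encodes a large coiled-coil protein. The comparisons ask which transcripts differ between KO and WT in 2 parental lines, whether 2 KO lines of one parent are alike, and which changes recur in the second parent. There were 2 OdG WT libraries (16867301 and 16570870 counts), 2 of OdG KO line 1 (18774032 and 16110028) and 2 of OdG KO line 2 (16392710 and 17797573). EG1 had 3 WT libraries (17657750, 17721101 and 19706599 counts) and 3 KO libraries (17678005, 17759834 and 17421260).

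Etl4 (mm10 chromosome 2, 19910207 to 20810535, plus strand) fell to 50.6% of its WT level in OdG KO (49.4 to 51.8 at ± 1 SE) and to 50.2% in EG1 KO (49 to 51.5 at ± 1 SE). OdG WT held 208 ± 3.21 CPM of Etl4, line 1 held 99.1 ± 2.69 and line 2 held 112 ± 3.25 (SD, n = 2 each). EG1 WT held 263 ± 2.75 CPM and EG1 KO 132 ± 1.34 (SD, n = 3 each). Every KO library lay below every WT library of its table, with raw counts of 1591 to 2034 against 3467 to 3630 in OdG and 2284 to 2352 against 4708 to 5147 in EG1. The log2 fold change was -0.98 ± 0.034 in OdG (adjusted p = 1.2e-13) and -0.99 ± 0.036 in EG1 (adjusted p = 7.8e-20). The difference between the 2 did not pass the threshold (0.00 ± 0.049, adjusted p = 0.98). Line 2 kept slightly more Etl4 than line 1 (log2 0.18 ± 0.043, adjusted p = 0.0032). The labels do not describe the edit, so these reads show how much transcript is counted and not whether it is functional.

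**Figure D1:**
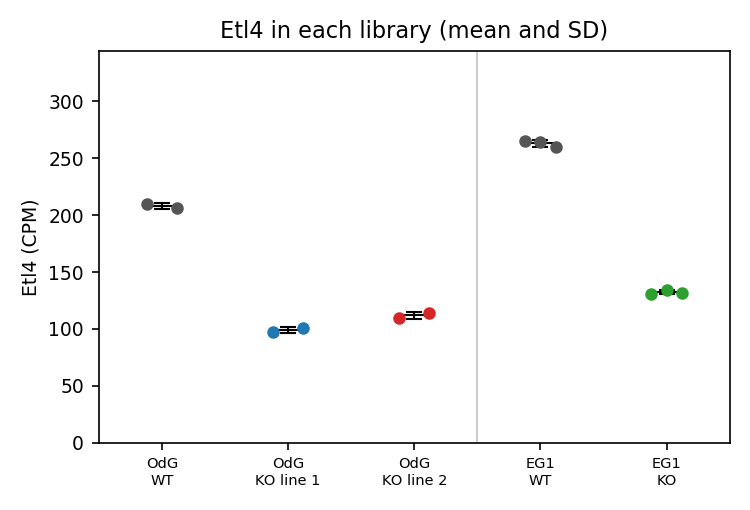
Etl4 in CPM (y axis) in each library, 1 point per library, grouped by line and genotype, with the group mean and SD as a bar; OdG and EG1 were scaled separately. KO libraries sit at 97.2 to 114 CPM in OdG and 131 to 134 CPM in EG1, below WT libraries at 206 to 210 and 260 to 265 CPM.

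In OdG KO, 20 of 22 glycolysis genes fell and 0 rose (20 also adjusted over the list alone; median log2 -0.91). Camera called the list (adjusted p = 4.9e-18), but not with an inter-gene correlation estimated from the data (adjusted p = 0.061 with an estimated correlation). Among those that fell were the glucose transporters Slc2a1 (2750 ± 14.5 CPM in WT against 902 ± 8.79 in line 1 and 860 ± 6.2 in line 2; log2 -1.64 ± 0.02) and Slc2a3 (log2 -0.90 ± 0.015), the lactate exporter Slc16a3 (log2 -2.16 ± 0.034) and the isomerase Gpi1 (log2 -1.18 ± 0.021). All 18 hypoxia response genes fell (18 adjusted over the list alone; median log2 -1.37; camera adjusted p = 1.5e-15, and adjusted p = 0.061 with an estimated correlation), including Ero1l (log2 -2.03 ± 0.03), Ndrg1 (log2 -1.97 ± 0.037) and Bnip3 (log2 -1.81 ± 0.038). The 2 lists share members such as Slc2a1.

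Of 18 naive pluripotency genes, 16 rose and 2 fell in OdG KO (the same numbers adjusted over the list alone; median log2 0.40). The camera call (adjusted p = 2.2e-06) was lost at adjusted p = 0.073 with an estimated correlation. Nanog, a core factor of the naive state, was at 646 ± 7.85 CPM in WT against 973 ± 21 in line 1 and 963 ± 7.17 in line 2 (log2 0.58 ± 0.025). Fbxo15 (log2 0.76), Nr0b1 (log2 0.75) and Klf5 (log2 0.76) also rose. Of 15 core pluripotency genes 13 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 2.3e-06, and adjusted p = 0.14 with an estimated correlation). Trim28 (log2 0.69), Lin28a (log2 1.00) and Utf1 (log2 1.57) rose and the Nodal co-receptor Tdgf1 fell (log2 -0.59). Nuclear oxidative phosphorylation genes rose by small amounts (30 rose and 4 fell of 55, the same adjusted over the list alone; median log2 0.11), for example Atp5g1 (log2 0.62), Uqcrq (log2 0.44), Cycs (log2 0.46) and Cox5a (log2 0.32). Their camera adjusted p was 6e-04, and adjusted p = 0.49 with an estimated correlation. G1/S and DNA replication genes did likewise (12 rose and 4 fell of 24, the same adjusted over the list alone), with Mcm2 (log2 0.43), Ccne1 (log2 0.51), Ung (log2 0.44) and Mcm5 (log2 0.35). Their camera adjusted p was 0.012, and adjusted p = 0.19 with an estimated correlation. In line 1 alone the G1/S list was not called (10 rose and 3 fell, adjusted p = 0.072, but 0.03 without OdG WT replicate 2).

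Cholesterol synthesis genes fell in OdG KO (16 fell and 0 rose of 21, the same adjusted over the list alone), with Insig1 (log2 -1.07), Dhcr7 (log2 -1.15) and Hmgcs1 (log2 -0.80). Their camera adjusted p was 2.4e-07, and adjusted p = 0.073 with an estimated correlation. Primitive endoderm markers fell (10 of 15, none rose, 10 adjusted over the list alone; camera adjusted p = 0.0045, and adjusted p = 0.18 with an estimated correlation), with the basement membrane genes Sparc (log2 -0.55) and Lama1 (log2 -0.56) lower in both lines. Col4a2 and Col4a1 fell in line 2 (log2 -1.44 and -1.12), while in line 1 they were at log2 0.16 (adjusted p = 0.048) and 0.11 (adjusted p = 0.13). The endoderm list was not called in line 1 (1 rose and 5 fell of 15, and 0 and 5 adjusted over the list alone, adjusted p = 0.1). Of 15 immediate early genes 10 fell and 2 rose (the same adjusted over the list alone), with Dusp1 (log2 -0.74), Jun (log2 -1.01), Klf6 (log2 -0.53) and Ier3 (log2 -0.95) falling. Their camera adjusted p was 0.0045, and adjusted p = 0.34 with an estimated correlation. With the 4 KO libraries as a single group, so that the spread between lines enters the error, Hmgcs1 (adjusted p = 0.072), Sparc (0.15), Col4a2 (0.54) and Col4a1 (0.49) lost their OdG KO calls.

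As the mean of both lines the 2-cell-like list rose in OdG KO (12 of 15, none fell, 12 adjusted over the list alone; median log2 1.52; camera adjusted p = 0.0025, and adjusted p = 0.34 with an estimated correlation), with Zscan4d (log2 1.48), Zscan4a (log2 1.68), Zscan4c (log2 1.66) and Usp17le (log2 1.83). Line 1 by itself had 1 of 15 higher and 0 adjusted over the list alone (list adjusted p = 0.24), and these 4 genes did not pass there (adjusted p = 0.12, 0.052, 0.077 and 0.068). Germline genes silenced by DNA methylation also rose in the mean (11 rose and 2 fell of 17, the same adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.39 with an estimated correlation), with Rpl10l (log2 0.57) and Tex19.1 (log2 0.39) higher in both lines. The lines went apart for this list, with 2 higher and 8 lower in line 1 (the same adjusted over the list alone; median log2 -0.42, list adjusted p = 0.12) against 15 higher and 0 lower in line 2. Sycp1 (log2 1.15) and Slc25a31 (log2 0.87) were at log2 0.07 (adjusted p = 0.66) and -0.07 (adjusted p = 0.75) in line 1. The germline call was lost without OdG WT replicate 1 (adjusted p = 0.076). With the KO libraries as a single group Zscan4d, Zscan4a, Zscan4c and Usp17le lost their OdG KO calls (adjusted p = 0.1, 0.078, 0.074 and 0.071), and so did Sycp1 and Slc25a31 (0.16 and 0.21).

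Within the limits of the rule for named genes, the largest rises in OdG KO were at genes nearly absent from the WT libraries. Gnpda2 (chromosome 5, 69574998 to 69592332) had 0 and 1 counts in WT and 1369 over the 4 KO libraries, a ratio of 683 (95% interval 122 to 27000). Its neighbour Guf1 (chromosome 5, 69556910 to 69574652), a mitochondrial translation factor, had 6 counts in WT and 3135 in KO, a ratio of 261 (120 to 711). The transcription factor gene Tfap2c (chromosome 2, 172545678 to 172558622) had 13 counts in WT, with a ratio to WT of 27.4 in line 1 (15.8 to 52) and 296 in line 2 (173 to 555). In EG1 WT and KO, Gnpda2 was at 16.4 ± 1.63 and 14.6 ± 1.37 CPM, Guf1 at 40.1 ± 1.14 and 36.3 ± 2.7, and Tfap2c at 86.7 ± 2.69 and 85.5 ± 1.23. The next largest rises within those limits were Spry4 (log2 2.82 ± 0.3), a feedback inhibitor of FGF and ERK signalling, and Enox1 (log2 2.72 ± 0.24). Larger rises outside them, such as Pramel7 (log2 3.62), are not ranked here. They were followed by the neurofilament gene Nefm (log2 2.68 ± 0.17), LOC105246506 (log2 2.48 ± 0.13) and the X-linked homeobox gene Rhox5 (log2 2.34 ± 0.083). The largest falls within the same limits were Cacna1h, a T-type calcium channel gene (15.4 ± 1.85 CPM in WT, 0.866 ± 0.302 in line 1, 1.93 ± 0.112 in line 2; log2 -3.58 ± 0.15), Ndufa4l2 (log2 -3.50 ± 0.14) and Nxph4 (log2 -3.22 ± 0.19). They were followed by Card14 (log2 -3.11 ± 0.18), the adrenomedullin gene Adm (log2 -3.08 ± 0.16), the FGF receptor gene Fgfr3 (log2 -2.84 ± 0.084), the NMDA receptor gene Grin1 (log2 -2.74 ± 0.12) and Fhad1 (log2 -2.71 ± 0.19). Adjusted p for these 16 genes was at most 3.7e-07. In each all 4 KO libraries lay on one side of both WT libraries, as the rule for named genes required. Rhox5 alone of them lost its call with the KO libraries as a single group (adjusted p = 0.086).

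Over all genes, 8638 of 14413 (59.9%) differed between OdG KO and WT, 4241 higher and 4397 lower, most by little (median absolute log2 fold change 0.40). With a log2 change of at least 1, 1281 remained past the threshold, 373 higher and 908 lower, and a test against a 2-fold change called 80 higher and 284 lower. All OdG KO values rest on 2 WT libraries in which Guf1, Gnpda2 and Tfap2c were nearly absent, unlike in both KO lines and in EG1. Treating the 4 KO libraries as a single group called 4609. Of the lists not called in OdG KO, those of cell state, with adjusted p, were formative and primed pluripotency (0.22; 4 rose and 2 fell of 14, and 4 and 1 adjusted over the list alone), primitive streak and mesoderm (0.45; 3 and 6 of 14), neural ectoderm (0.55; 3 and 3 of 10) and trophoblast (0.37; 3 and 6 of 15). Those of metabolism, cell cycle and stress were tricarboxylic acid cycle (0.066; 12 and 4 of 20, and 13 and 4 adjusted over the list alone), p53 targets (0.32; 3 and 9 of 22), mitosis and cytokinesis (0.34; 11 and 8 of 30) and integrated stress response (0.66; 11 and 9 of 22). The others were maternally expressed imprinted (0.39; 5 and 10 of 18), paternally expressed imprinted (0.39; 7 and 11 of 22), feeder markers (0.32; 2 and 6 of 13), epithelial adhesion (0.45; 6 and 7 of 18), Wnt targets (0.73; 3 and 5 of 16) and MEK/ERK targets (0.15; 10 and 4 of 14). Where no second pair is given, the counts were the same adjusted over the list alone.

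**Figure D2:**
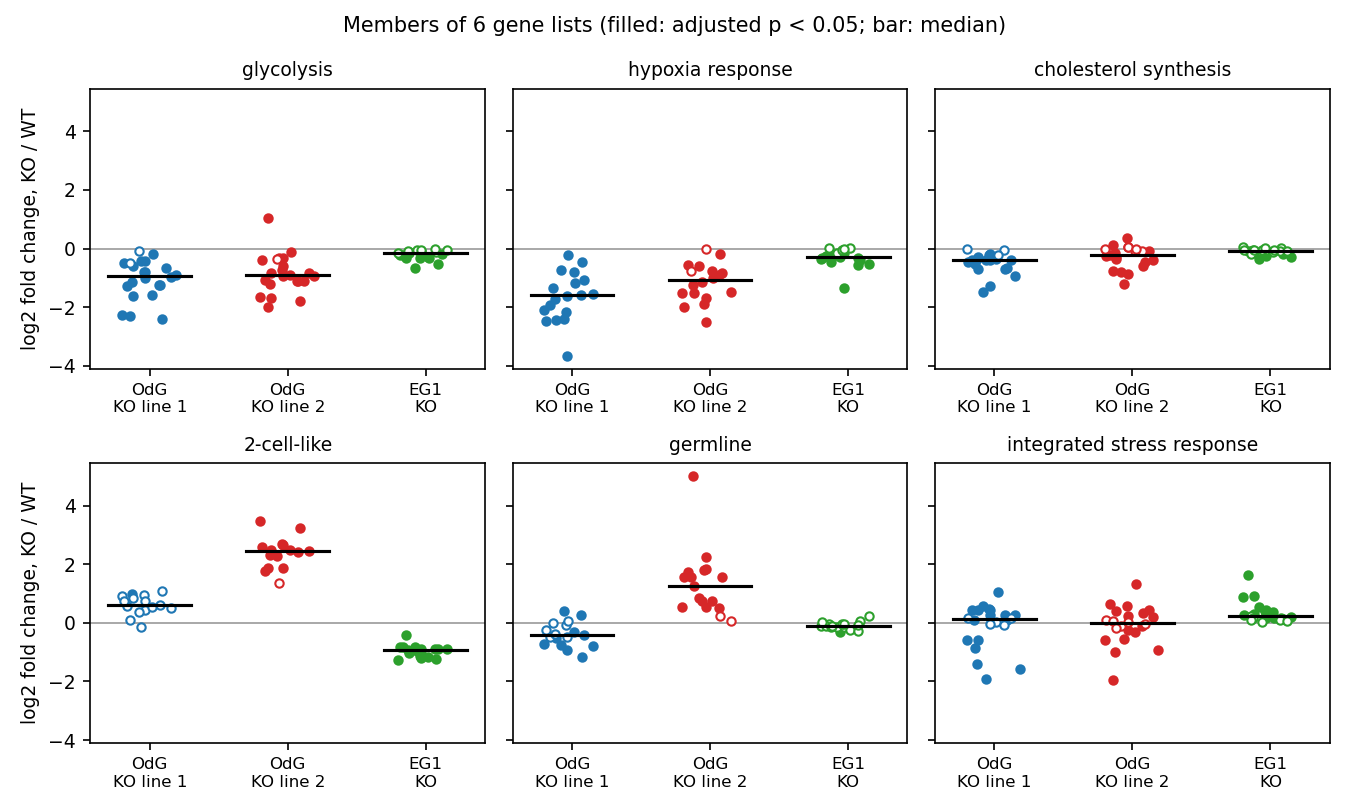
Log2 fold change of KO over WT (y axis) for each tested member of 6 gene lists in OdG KO line 1, OdG KO line 2 and EG1 KO; filled points passed an adjusted p of 0.05 and the bar is the list median. Glycolysis and hypoxia members lie mostly below 0 in all 3, with hypoxia medians of -1.60, -1.08 and -0.30, while 2-cell-like members lie above 0 in line 2 (median 2.45) and below 0 in EG1 (median -0.92).

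Each KO line was compared with the shared OdG WT to see which changes both carry. Glycolysis, hypoxia response and cholesterol synthesis genes fell in both lines (20 of 22, 18 of 18 and 18 of 21 in line 1, and 20 of 22, 16 of 18 and 13 of 21 in line 2). The 3 list calls held in line 1 (adjusted p = 0.046 with an estimated correlation for each) and were lost in line 2 (adjusted p = 0.05, 0.05 and 0.13 with an estimated correlation). In line 2, 1 glycolysis and 2 cholesterol synthesis genes rose. Adjusted over the list alone, these falls were 20 and 20, 18 and 16, and 19 and 13. Egln3, an oxygen-sensing prolyl hydroxylase gene, showed log2 -2.39 in line 1 and -1.14 in line 2. In line 1 the lists of core and naive pluripotency and oxidative phosphorylation rose (13, 15 and 33 members rose and 1, 1 and 0 fell). These calls were lost at adjusted p = 0.13, 0.053 and 0.56 with an estimated correlation. Adjusted over the list alone 13, 15 and 34 rose and 1, 1 and 1 fell. Sall4 was at log2 0.60 and Prdm14 at log2 0.97. Immediate early genes fell in line 1 (10 fell and 2 rose of 15, and 12 and 2 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation), although Myc rose (log2 1.20). Maternally expressed imprinted genes also fell in line 1 (8 of 18, none rose, 8 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), including Igf2r (log2 -0.62), Ascl2 (log2 -1.45), Ppp1r9a (log2 -0.54) and Gnas (log2 -0.26).

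Line 1 differed from WT at 7616 genes (3859 higher, 3757 lower), of which 1087 had a log2 change of at least 1 (181 higher, 906 lower). Of its 8 called lists, 3 held with an estimated correlation.

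In line 2 the 2-cell-like list rose (14 of 15, 14 adjusted over the list alone; median log2 2.45; adjusted p = 0.16 with an estimated correlation). Examples are Zscan4d at 7.53 ± 0.389 CPM against 1.38 ± 0.065 in WT, Zscan4f (log2 2.58) and Tcstv3 (log2 3.46). Germline genes rose (15 of 17, 15 adjusted over the list alone; median log2 1.27; adjusted p = 0.15 with an estimated correlation), including the synaptonemal complex gene Sycp1 at 54.3 ± 2.37 CPM against 11.6 ± 2.23 in WT, and Taf7l (log2 1.27). Line 2 also had higher core and naive pluripotency (12 rose and 2 fell of 15, and 14 rose and 2 fell of 18; adjusted p = 0.13 with an estimated correlation for each). It had higher G1/S genes (14 and 3 of 24, with Mcm7 at log2 0.41) and higher oxidative phosphorylation (22 and 8 of 55, with Ndufv2 at log2 0.32), where the values were adjusted p = 0.16 and 0.66 with an estimated correlation. It had lower primitive endoderm (9 of 15 fell) and lower immediate early genes (10 fell and 2 rose of 15, with Egr1 at log2 -2.04), where they were adjusted p = 0.16 and 0.30 with an estimated correlation. These counts were the same adjusted over the list alone except that 7 oxidative phosphorylation genes fell. Line 2 differed from WT at 8628 genes (4329 higher, 4299 lower), 1773 of them with a log2 change of at least 1 (692 higher, 1081 lower). The oxidative phosphorylation call was lost without OdG WT replicate 1, line 1 replicate 1 or line 2 replicate 1 (adjusted p = 0.43, 0.052 and 0.11). Of the 11 lists called in line 2, 0 held with an estimated correlation, by camera.

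The 2 lines shared 5496 genes called in the same direction against WT (2796 higher and 2700 lower), and 366 were called in opposite directions. Independent lists of these sizes would share 1160 higher and 1120 lower genes. Unchanged groups, simulated with WT included and with the spread between libraries alone, shared 0.6 genes on average and at most 2. Such simulations hold no difference between stocks or cultures. They cannot tell a shared KO effect from a WT that differs from the parent of both KO lines. Log2 fold changes correlated across genes, which are not independent replicates, at r = 0.64 (covariance 0.298), against r = 0.50 (covariance 0.017) in the simulations. With each line set against a different WT library, chosen after seeing the data, 4793 or 4841 genes were called in the same direction, depending on which line took which library. The correlation was then r = 0.54 or 0.55 and the covariance 0.279 or 0.284. A lone WT library was assumed to vary like the other groups, and both WT libraries are of 1 line.

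Line 2 and line 1 nevertheless differed from each other at 5454 genes (2680 higher and 2774 lower in line 2), 975 of them with a log2 difference of at least 1 (709 higher, 266 lower). The non-coding RNA genes Meg3 and Rian of the imprinted Dlk1-Dio3 region on chromosome 12 had 2398 and 1901 counts in line 2 against 24 and 20 in line 1, ratios of 99.7 (95% interval 66.9 to 156) and 94.9 (61.3 to 156). The X-linked Rhox13 had 309 counts in line 2 and 6 in line 1 (ratio 51.4, 23.3 to 141), and Fkbp6, a gene needed in meiosis, was also higher in line 2 (log2 4.90 ± 0.18). Lower in line 2 were Vnn1 (log2 -2.91 ± 0.13), Igf2os (log2 -2.74 ± 0.26), the imprinted growth factor gene Igf2 (17 ± 0.49 against 98.6 ± 0.19 CPM; log2 -2.54 ± 0.056) and Thbs1 (log2 -2.24 ± 0.22). H19, the imprinted neighbour of Igf2, named after its values were seen, was higher in line 2 (26.4 ± 0.746 against 2.93 ± 0.527 CPM; log2 3.18 ± 0.16). Adjusted p for these 9 genes was at most 3.4e-07.

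By list, all 17 germline genes were higher in line 2 than in line 1 (17 adjusted over the list alone; median log2 1.6, camera adjusted p = 5.9e-15, and adjusted p = 0.15 with an estimated correlation). So were 14 of 15 2-cell-like genes (14 adjusted over the list alone; median log2 1.80, adjusted p = 6e-07, and adjusted p = 0.17 with an estimated correlation). Higher in line 2 were also hypoxia response (13 higher, 1 lower of 18), cholesterol synthesis (14 and 2 of 21) and glycolysis (13 and 3 of 22), at adjusted p = 0.15, 0.15 and 0.26 with an estimated correlation. The same held for maternally expressed imprinted (10 and 2 of 18), MEK/ERK targets (8 and 1 of 14) and formative and primed pluripotency genes (6 and 2 of 14), at adjusted p = 0.16, 0.23 and 0.43 with an estimated correlation. Lower were oxidative phosphorylation (16 lower, 1 higher of 55), paternally expressed imprinted (10 and 2 of 22) and trophoblast genes (8 and 3 of 15), with adjusted p = 0.76, 0.23 and 0.26 with an estimated correlation. Adjusted over the list alone the counts were the same, except for oxidative phosphorylation (14 lower, 1 higher), maternally (10 higher, 3 lower) and paternally expressed imprinted genes (11 lower, 2 higher) and MEK/ERK targets (8 higher, 2 lower). Camera adjusted p for these 9 lists was at most 0.049. These list tests were added after seeing the data. None of the 11 calls held with an estimated correlation.

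**Figure D3:**
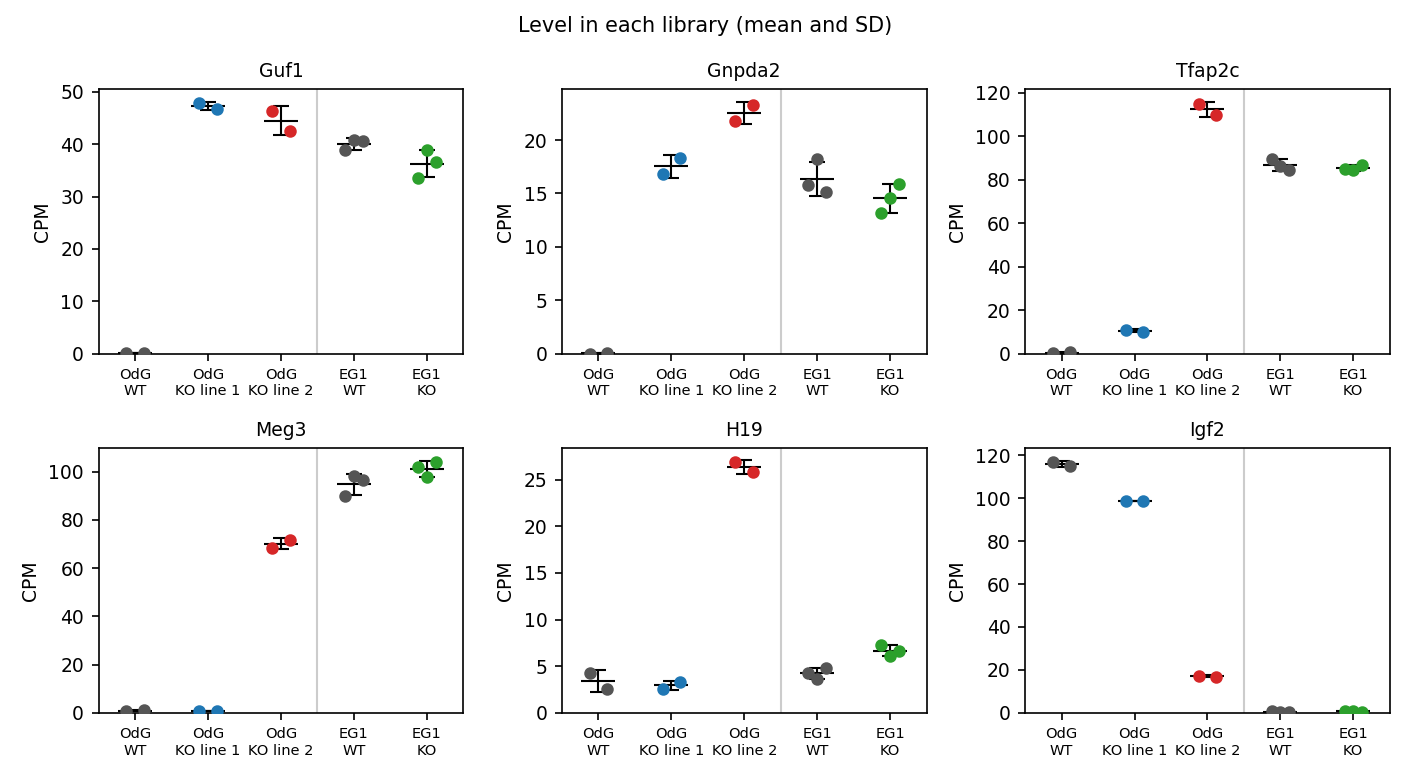
CPM (y axis, linear) of Guf1, Gnpda2, Tfap2c, Meg3, H19 and Igf2 in each library, 1 point per library, with the group mean and SD; OdG and EG1 were scaled separately. Guf1 and Gnpda2 are near 0 only in the 2 OdG WT libraries, and line 2 stands apart from line 1 at Tfap2c, Meg3, H19 and Igf2.

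In EG1 KO the 2-cell-like list fell, the integrated stress response rose and hypoxia genes fell. These calls held (adjusted p = 0.0091, 0.027 and 0.0091 with an estimated correlation). EG1 had 1 KO line, so changes particular to that line cannot be told apart from an effect of Etl4 loss. All 17 tested 2-cell-like genes fell (17 adjusted over the list alone; median log2 -0.92). They included Zscan4a (38 ± 1.94 CPM in WT, 18.8 ± 1.5 in KO; log2 -1.02 ± 0.07), Zscan4d (log2 -0.91 ± 0.081), Zscan4c (log2 -0.84 ± 0.087) and Usp17le (log2 -1.21 ± 0.11). Of 21 integrated stress response genes 15 rose and 0 fell (16 adjusted over the list alone; median log2 0.22). They included the glutathione-degrading enzyme gene Chac1 (6.96 ± 0.499 against 21.6 ± 2.12 CPM; log2 1.63 ± 0.099), the pseudokinase gene Trib3 (log2 0.90 ± 0.082), Pck2 (log2 0.45) and the serine synthesis gene Psat1 (log2 0.30). Atf4, which encodes the transcription factor of that response and was named after its values were seen, rose from 212 ± 6.54 to 322 ± 1.74 CPM (log2 0.60 ± 0.035). Hypoxia response genes fell (13 of 17, none rose, 13 adjusted over the list alone; median log2 -0.30), including Ndrg1 (log2 -0.56), Egln3 (log2 -0.45), P4ha2 (log2 -0.53) and Slc2a1 (609 ± 15.9 against 485 ± 15.7 CPM; log2 -0.33 ± 0.033). Glycolysis genes fell (14 of 21, none rose, 16 adjusted over the list alone; median log2 -0.16), with Gpi1 (log2 -0.24), Pgk1 (log2 -0.21) and Aldoc (log2 -0.52). That call was lost at adjusted p = 0.062 with an estimated correlation.

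Cholesterol synthesis also fell in EG1 KO (5 of 21, 7 adjusted over the list alone), with Insig1 (log2 -0.24), Msmo1 (log2 -0.29), Dhcr7 (log2 -0.34) and Cyp51 (log2 -0.17), and the call held (adjusted p = 0.038 with an estimated correlation). A further 4 lists rose with few members past the threshold, and lost their calls with an estimated correlation. They were core pluripotency (5 rose and 1 fell of 15, and 5 and 2 adjusted over the list alone; L1td1 log2 0.27, Lin28a 0.45, Utf1 0.35, Gdf3 0.18) and primitive endoderm (3 of 13; Col4a1 log2 0.34, Col4a2 0.31, Lama1 0.13), at adjusted p = 0.25 and 0.21 with an estimated correlation. They were also G1/S (3 of 24; Ccne1 log2 0.20, Cdk2 0.17, Mcm5 0.12) and mitosis (2 of 30, and 3 adjusted over the list alone; Cdc20 log2 0.26, Plk1 0.13), at adjusted p = 0.23 and 0.25 with an estimated correlation. Primitive endoderm and G1/S had 3 risen members each adjusted over the list alone. In the same lists Lamb1 (log2 0.09, adjusted p = 0.22), Mcm2 (log2 0.08, adjusted p = 0.12), Aurka (log2 0.11, adjusted p = 0.054) and Cdk1 (log2 0.10, adjusted p = 0.12) did not pass. Of the genes named as risen, Lama1 lost its call without any 1 of 5 libraries (each WT library, KO replicates 1 and 3; adjusted p from 0.062 to 0.15). Plk1 lost it without any 1 of 4 (each WT library, KO replicate 1; from 0.075 to 0.18) and Mcm5 without any 1 of 3 (WT replicates 2 and 3, KO replicate 1; from 0.069 to 0.12). The fall of Cyp51 was lost without WT replicate 3 (adjusted p = 0.076). Camera adjusted p was 9.7e-34 for the 2-cell-like list, 2.1e-23 for the stress response, 2.5e-17 for hypoxia, 2.3e-20 for glycolysis and 6.9e-06 for cholesterol synthesis. It was 0.011, 0.0076, 0.0053 and 0.011 for the 4 lists that rose with few members.

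Within the limits of the rule for named genes, the largest rises in EG1 KO besides Chac1 and Trib3 were Sema5a, a semaphorin (log2 1.35 ± 0.12), the trophoblast transcription factor gene Gata3 (log2 1.14 ± 0.15), and Dcdc2a (log2 1.12 ± 0.15). They were followed by the X-linked ubiquitin ligase gene Mid1 (log2 1.06 ± 0.13), Herpud1, a gene of endoplasmic reticulum stress (log2 0.93 ± 0.084) and Atf3 (log2 0.88 ± 0.19). The largest falls within the same limits were Bphl (log2 -1.78 ± 0.15), Cacna1h (log2 -1.38 ± 0.17), Zfp352 (log2 -1.23 ± 0.13) and Usp17le. They were followed by Usp17lc (log2 -1.15 ± 0.12), the insulin receptor gene Insr (39.1 ± 0.86 against 18.1 ± 2.29 CPM; log2 -1.11 ± 0.073), BB287469 (log2 -1.10 ± 0.17) and Pramef25 (log2 -1.05 ± 0.087). Adjusted p for these 16 genes was at most 0.0025. In each all 3 KO libraries lay on one side of all 3 WT libraries, as the rule for named genes required.

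Over all genes, 1074 of 14016 (7.7%) differed in EG1, 505 higher and 569 lower, and 55 had a log2 change of at least 1 (11 higher, 44 lower). The count was lower by over 1.5 times without any one WT library (638 without replicate 1, 672 without replicate 2 and 658 without replicate 3), and DESeq2's Wald test called 657. Of the lists not called in EG1 KO, those of pluripotency, with adjusted p, were naive (0.89; 2 rose and 0 fell of 18) and formative and primed pluripotency (0.91; 1 and 0 of 13, and 1 and 2 adjusted over the list alone). Those of other cell types were primitive streak and mesoderm (0.88; 0 and 0 of 11), neural ectoderm (0.27; 1 and 0 of 7, and 1 and 1 adjusted over the list alone) and trophoblast (0.068; 2 and 0 of 12, and 4 and 1 adjusted over the list alone). Germline genes (0.075; 0 and 1 of 16, and 0 and 2 adjusted over the list alone) and oxidative phosphorylation (0.15; 1 and 0 of 55, and 0 and 0 adjusted over the list alone) were not called either. Germline genes were called without KO replicate 2 or 3 (adjusted p = 0.038 and 0.043), and oxidative phosphorylation without WT replicate 1 or 3 or KO replicate 3 (adjusted p = 0.015, 0.024 and 0.014). The same was true of tricarboxylic acid cycle (0.89; 1 and 0 of 20, and 1 and 1 adjusted over the list alone) and p53 targets (0.47; 1 and 3 of 23, and 1 and 4 adjusted over the list alone). It was true of maternally (0.88; 1 and 1 of 16) and paternally expressed imprinted (0.88; 2 and 2 of 23, and 3 and 3 adjusted over the list alone) and of feeder markers (0.37; 2 and 0 of 8). The others were immediate early genes (0.91; 3 and 2 of 15, and 3 and 4 adjusted over the list alone), epithelial adhesion (0.24; 0 and 1 of 18, and 1 and 1 adjusted over the list alone), Wnt targets (0.11; 1 and 1 of 13, and 1 and 3 adjusted over the list alone) and MEK/ERK targets (0.71; 0 and 1 of 13). Counts with no second pair were again the same adjusted over the list alone.

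Changes that recurred in the second parental line were asked for among the 13630 genes tested in both. There 715 genes changed in the same direction in OdG KO and EG1 KO, and 148 in opposite directions. The 366 genes higher in both compare with 154 for independent lists (Fisher's exact test across genes, odds ratio 6.49, p = 4.66e-87). The 349 lower in both compare with 169 (Fisher's exact test, odds ratio 4.13, p = 4.38e-58), where genes are not independent replicates. The WT libraries of the 2 lines are separate. Log2 fold changes correlated across genes at Pearson r = 0.27 and Spearman rho = 0.35. Higher in both were Mid1 (log2 1.83 in OdG and 1.06 in EG1), the prostaglandin transporter gene Slco2a1 (0.76 and 0.84) and the glycine transporter gene Slc6a9 (0.75 and 0.74). So were the endocytic receptor gene Lrp2 (2.27 and 0.72), Pramel7 (3.62 and 0.71) and Cd3e (1.86 and 0.69). Pramel7 lost its OdG call with the KO libraries as a single group (adjusted p = 0.054). Lower in both were Cacna1h (-3.58 and -1.38), Etl4, Ndufa4l2 (-3.50 and -0.95), the glycogen-targeting subunit gene Ppp1r3c (-1.0 and -0.94), Lbh (-1.59 and -0.87) and Grin1 (-2.74 and -0.84). With a log2 change of at least 1 in each, 1 gene was higher in both and 11 were lower in both. With each OdG KO line required past the threshold, 598 genes were shared, and without EG1 WT replicate 1, 2 or 3 the shared count was 409, 443 or 432.

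**Figure D4:**
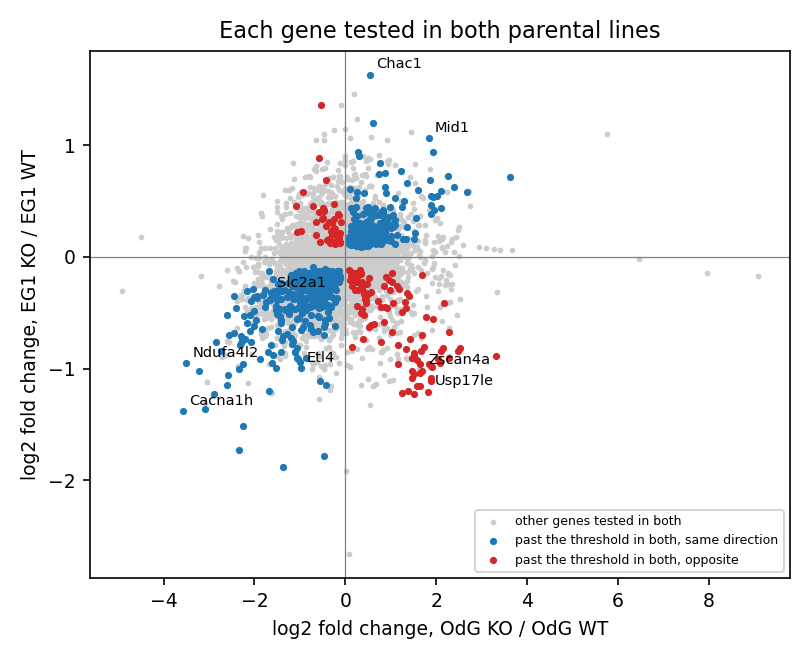
Log2 fold change of OdG KO over WT (x axis) against that of EG1 KO over WT (y axis) for the 13630 genes tested in both, with genes past the threshold in both coloured by whether the directions match. The 715 matching genes outnumber the 148 opposite ones, and Zscan4a and Usp17le are among the opposite ones.

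The change from WT to KO differed between OdG and EG1 at 5958 of 14977 genes (3030 with a higher and 2928 with a lower log2 change in OdG). Of them, 968 differed by a log2 of at least 1 (386 higher, 582 lower). The test uses only the spread between libraries, so differences between WT stocks or between single KO lines enter this count. Glycolysis and hypoxia genes fell further in OdG than in EG1 (20 of 22 and 17 of 18 with a lower change; median differences -0.74 and -1.23). So did cholesterol synthesis genes (13 of 21; -0.23). The glycolysis gene Aldoc was at 108 CPM in OdG WT against 28.3 in EG1 WT, each scaled within its table. The hypoxia gene Adm was at 11.9 against 4.84 CPM. For these genes the larger fall started from a higher WT level, and the other members were not compared in this way. The 2-cell-like list had a higher change in OdG, as the mean of both lines, than in EG1 (16 of 17; median difference 2.59). It fell in EG1 and rose in line 2, and was not called in line 1 (adjusted p = 0.24). The integrated stress response was lower in OdG relative to EG1 (14 of 22; -0.26). Adjusted over the list alone these counts were 20, 17, 14, 17 and 15. Core and naive pluripotency, primitive endoderm and germline lists also differed, and all 9 of these calls held with an estimated correlation (highest adjusted p = 0.049 with an estimated correlation). Formative and primed pluripotency, oxidative phosphorylation and immediate early genes were called only with the preset correlation (adjusted p = 0.25, 0.50 and 0.067 with an estimated correlation). OdG and EG1 libraries lie in separate tables, so line and any sequencing batch cannot be told apart in levels, while each KO effect rests on WT libraries of its own table.

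Single genes with the largest such differences included Gnpda2, Guf1 and Tfap2c, the 3 genes nearly absent from OdG WT. Ndufa4l2 fell further in OdG (difference in log2 -2.55 ± 0.2). Krt80 fell in OdG (log2 -2.39 ± 0.18) and had only 9 counts over the EG1 WT and 14 over the EG1 KO libraries (difference -3.09 ± 0.68). Peg13 had 0 counts in OdG WT, 3 in line 1 and 13 in line 2 against 368 in EG1 WT and 398 in EG1 KO. St8sia2 had 336 counts in OdG WT and 0 in EG1 WT. Igf2os had 140 counts in OdG WT and 2 in EG1 WT. For these last 3 genes the difference rests on a group at or near 0, where a fitted fold depends on the prior count and is no bound. Their calls were lost without any 1 of several libraries, namely OdG WT replicate 1 or 2 or line 1 replicate 2 for Peg13 (adjusted p from 0.073 to 0.094). For the others they were any EG1 WT library or EG1 KO replicate 2 for St8sia2 (from 0.057 to 1) and EG1 WT replicate 1 or 3 or EG1 KO replicate 1 for Igf2os (from 0.076 to 0.22).

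Chromosome-wide shifts, which would accompany gain or loss of a chromosome in part of the cells, were not detected. Camera called 0 of 20 chromosomes in each of the 6 comparisons (0 also with an estimated correlation). At an unadjusted p under 0.05 it found 1 chromosome for line 2 versus line 1 and 0 in each other comparison. Chromosome medians lay between -0.08 and 0.10 on the log2 scale. Because libraries are scaled to their totals, a doubling of the whole chromosome set would leave no trace here, so ploidy was not measured.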

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

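The tests of counts, of labels, of neighbouring genes, of the OdG WT stock, of shared reads and of EG1 cells in line 2 were chosen only after the result was seen, as were the list tests for line 2 versus line 1 and for OdG versus EG1. The tests of GC content and length, of culture labels, of the second germline list and of other sample splits were written before.

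The change from WT to KO differed between OdG and EG1, by the interaction test, at 5958 genes, and line 2 differed from line 1 at 5454 genes. For OdG minus EG1, the median log2 differences of the lists were 0.33 for core and 0.30 for naive pluripotency, -0.70 for primitive endoderm, 2.59 for 2-cell-like genes, 0.50 for germline genes, -0.74 for glycolysis, 0.07 for oxidative phosphorylation, -0.26 for the integrated stress response, -1.23 for hypoxia, -0.23 for cholesterol synthesis and -0.53 for immediate early genes. For line 2 minus line 1 the medians were 1.80 for 2-cell-like genes, 1.6 for germline genes, 0.10 for glycolysis, -0.06 for oxidative phosphorylation, 0.36 for hypoxia, 0.21 for cholesterol synthesis and 0.40 for maternally expressed imprinted genes.

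Among genes with the largest changes in OdG, the log2 difference between the OdG and EG1 effects was 9.25 for Gnpda2, 8.10 for Guf1, 6.48 for Tfap2c, 2.26 for Spry4, 2.12 for Enox1, 2.09 for Nefm, 2.23 for LOC105246506, 2.18 for Rhox5, -2.21 for Cacna1h, -2.55 for Ndufa4l2, -2.21 for Nxph4, -1.72 for Adm, -2.08 for Fgfr3, -1.91 for Grin1 and -1.82 for Fhad1. Among genes with the largest changes in EG1 it was -1.10 for Chac1, -1.89 for Sema5a, -1.16 for Gata3, 0.76 for Mid1, -0.66 for Herpud1, -0.61 for Trib3, -1.47 for Atf3, 1.31 for Bphl, 2.74 for Zfp352, 3.03 for Usp17le, 2.79 for Usp17lc, 0.54 for Insr, 2.13 for BB287469 and 2.55 for Pramef25. Genes changed the same way in both lines still differed in size, by 1.54 for Lrp2, 2.90 for Pramel7, 1.17 for Cd3e and -0.72 for Lbh. The fitted differences for Peg13 (4.54), St8sia2 (-4.58), Krt80 (-3.09) and Igf2os (-2.89) rest on groups with few or 0 counts, as those for Gnpda2 and Guf1 do, so that they depend on the prior count and are no bounds. Spry4 had too few counts in EG1 to be tested there, so its difference is also uncertain (SE 0.84). Between line 2 and line 1 the log2 differences were 6.62 for Meg3, 6.55 for Rian, 5.63 for Rhox13, 4.90 for Fkbp6, -2.91 for Vnn1, -2.74 for Igf2os, -2.54 for Igf2 and -2.24 for Thbs1.

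Guf1 and Gnpda2, 345 bp apart on chromosome 5, held 7 counts together in the OdG WT libraries. At the CPM of the KO libraries 2249 counts would be expected there, which argues against too few counts, and 0 OdG libraries had an Etl4 CPM nearer the mean of the other genotype, which argues against swapped labels. Of 43 other tested genes within 5 Mb, 3 were under 25% of their KO level in OdG WT, namely Chrna9 (18.3%), Kctd8 (23.4%) and Cox7b2 (0%), and the last 2 are the nearest tested genes before (0.22 Mb) and after (1.85 Mb) the pair. A local loss around the pair in the OdG WT cells may therefore account for its absence, as a hypothesis found and tested on the same data, and its extent is open because Kctd8 and Cox7b2 are weakly expressed. It does not bear on Tfap2c, which lies on chromosome 2.

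Glycolysis and hypoxia genes fell in the KO of both parental lines (adjusted p = 0.061 for each in OdG, and 0.062 and 0.0091 in EG1, with an estimated correlation), with 25 of 36 members lower in EG1, which has its own WT libraries. After subtracting trends with GC content, transcript length and expression, 4 of 4 list medians stayed below the range of 10000 random lists (OdG -1.08 and -1.43, EG1 -0.23 and -0.34), which argues against those trends as the whole cause. An OdG WT stock that differs from the parent of the KO lines may account for part of the falls in OdG, as for any other OdG KO change, and cannot be told apart from the KO, because 0 OdG WT libraries held Guf1 and Gnpda2 at over 5% of their KO level. A difference in density or oxygen between KO and WT dishes cannot be told apart from the KO, because 0 labels give a culture day, density, oxygen level, passage or batch. An effect of Etl4 loss on these genes also stays open.

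Germline, 2-cell-like, H19 and Meg3 region transcripts were higher in line 2 than in line 1 (adjusted p = 0.15 and 0.17 for the first 2 lists with an estimated correlation). All 14 germline genes without near-identical copies were higher, which argues against shared reads for that list, while for 2-cell-like genes shared reads stay open because only 3 tested members (Zfp352, Tmem92 and Arg2, all 3 higher) lie outside the Zscan4, Usp17l, Tcstv and Dux families. Of 17 germline genes, 12 lay above both line 1 and EG1 WT, which argues against EG1 cells in line 2 as their source. Meg3 needs 72.2% EG1 cells, where 126 genes far higher in EG1 WT implied a median of 11.1% (quartiles 3.3% and 18.5%). The upper quartile lay just above the bound set for excluding a mixture, so that bound decided nothing. The shares implied by these genes still lie far below 72.2%, which argues against EG1 cells as the whole source of Meg3. A smaller share of EG1 cells stays open. Single genes, read on a common scale over all 12 libraries, did not imply a common share, as a mixture would. H19 was at 26 CPM in line 2 against 4.25 in EG1 WT and Trp53 implied 1.71%, while Igf2 implied 83.3%. Lower DNA methylation in line 2 may contribute, as a hypothesis, since a second germline list had a median log2 of 0.57 (16 higher and 2 lower of 24, random range -0.13 to 0.17), but methylation was not measured.

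For the 1074 genes called in EG1, the 10 splits of the 6 libraries are too few for a share under 0.05, and the highest other split called 1 gene.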

How the results depend on the processing

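Leaving out Guf1, Gnpda2 and Tfap2c, and setting line 1 and line 2 against different WT libraries, were chosen only after the result was seen. The first gave 8635 genes for OdG KO, and the other 4793 and 4841 genes called in the same direction in both lines. Dropping Guf1, Gnpda2 and Tfap2c could hardly change the count, so it does not test whether a different WT stock underlies the other changes. No named gene or list called in the main fit or in an alternative changed direction between the 2. Directions of results called in neither were not compared. The balance of higher and lower genes did change, and the causes were not tested except where stated. With DESeq2's Wald test the counts were 3237 for line 2 versus line 1, 657 for EG1 KO and 436 for genes changed the same way in both parental lines, and higher genes were 52% of those called in OdG KO, 55% in line 1, 53% in EG1 KO and 58.7% of those changed the same way in both (49.1%, 50.7%, 47% and 51.2% otherwise). With a log2 change of at least 1, a stricter threshold, they were 1281 for OdG KO (29.1% higher against 49.1%), 1087 for line 1 (16.7% against 50.7%), 1773 for line 2 (39% against 50.2%), 975 for line 2 versus line 1 (72.7% against 49.1%), 55 for EG1 KO (20% against 47%), 968 for the difference between parental lines (39.9% against 50.9%) and 12 for genes changed the same way in both (8.3% against 51.2%). Treating the OdG KO libraries as a single group gave 4609 genes. With an estimated correlation the lists called numbered 0 for OdG KO, 3 for line 1, 0 for line 2 and 4 for EG1 KO. Those counts depend on the few libraries of each fit as well as on the correlation, so they do not rank the comparisons. Leaving out each replicate gave 638 to 1213 genes for EG1 KO and 409 to 825 for those changed the same way in both, with the lowest counts without EG1 WT replicate 1, and a group left with 1 library was assumed to vary like the others. The other counts of genes stayed within 1.5 times. Of 316 results for single genes and lists, DESeq2's size factors changed 0 calls, no filter on low counts added 4, and leaving out some 1 library ended 9 and added 3. DESeq2's Wald test ended the call of 1 of the 216 results it was run on, a log2 change of at least 1 of 112 of 216, an estimated correlation of 32 of 100 list tests and a single KO group of 12 of 68, among them Rhox5, Pramel7, Sparc, Hmgcs1 and the 2-cell-like genes (Zscan4a, Zscan4c, Zscan4d, Usp17le). Same-numbered replicates did not deviate together (correlations from -0.05 to 0.04), so no shared effect of the number was seen. This cannot show that the numbers mark no shared culture or preparation. With the replicate block the counts were 8542 for OdG KO, 7515 for line 1, 8566 for line 2, 5334 for line 2 versus line 1, 906 for EG1 KO, 5863 for the difference between parental lines and 602 for both. With that block 3 calls of single genes or lists were lost, and the lists called in line 2 went from 11 to 10. Leaving out mitochondrially encoded genes was not run, as the tables hold 0 of them. Depth limits genes near 0 counts, such as Peg13, St8sia2 and Igf2os.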

Other observations

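The genes in this part other than Cd3e were chosen only after the result was seen. In EG1 KO the neighbouring T cell receptor subunit genes Cd3d, Cd3e and Cd3g rose together (log2 0.70 ± 0.072, 0.69 ± 0.098 and 0.84 ± 0.076). In OdG KO line 1 they rose too (log2 0.61, 1.20 and 0.62), while in line 2 Cd3e rose (log2 2.52) and Cd3d and Cd3g fell (log2 -0.51 and -0.38). The de novo DNA methyltransferase gene Dnmt3b rose in both parental lines (80.8 ± 1.13 CPM in OdG WT against 150 ± 5.34 in line 1 and 188 ± 2.26 in line 2; 111 ± 6.76 in EG1 WT against 136 ± 2.2 in EG1 KO). Its cofactor gene Dnmt3l rose in EG1 KO (log2 0.68 ± 0.059) and line 2 (log2 0.58) and fell in line 1 (log2 -0.30). In OdG KO the imprinted gene Mest (log2 1.07 ± 0.065) and the intermediate filament gene Vim (log2 0.91 ± 0.044) rose, and in EG1 KO they did not pass (log2 0.07, adjusted p = 0.55, and log2 0.11, adjusted p = 0.097).

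Levels of 4 genes of the p53 pathway were read on a common scale over all 12 libraries, with no test between the parental lines. Trp53 was at 50.6 ± 0.18 CPM in OdG WT, 57.6 ± 0.56 in line 1 and 63.5 ± 2.5 in line 2, against 406 ± 7.7 in EG1 WT and 420 ± 16 in EG1 KO. The p53 target Ccng1 was at 22.1 ± 0.18 CPM in OdG WT and 322 ± 6 in EG1 WT, Mdm2 at 58.9 ± 2.8 and 169 ± 8.4, and Cdkn1a at 232 ± 1.9 and 254 ± 2.2. Parental line and count table coincide, so line and any batch cannot be told apart in these levels.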
